A study of Mus musculus with 8 samples.

How the data were processed

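The data were 8 droplet libraries of mouse MGE or cortex, 1 per group: MGE at E13 labelled Dlx6-positive and Dlx6-negative, cortex at P2 (control and Mef2c cKO), and the areas labelled ALM and V1 at P10 and P28. Per the labels, E13 libraries were made from dissociated cells sorted for tdTomato and postnatal libraries from nuclei sorted for GFP. The deposited values were UMI counts per gene and barcode. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0.0 against mm10; the file headers name software version 3.0.2 for the postnatal libraries and none for E13. Annotated genes numbered 27998 in the E13 libraries, 28692 in the P2 control and 31053 in the other 5, and the settings behind this difference are not given in the sources used here. Coordinates came from GENCODE vM21 (mm10), which held 98.74% to 99.62% of the gene ids. The series design also names E14 CGE, which was not analysed here.

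Barcodes with under 500 genes or over 10% mitochondrial UMIs were removed, and then predicted doublets, at 0.8% per 1000 barcodes, which took 3.16% to 6.67% of barcodes. This kept 6527 of 6914 and 4208 of 4362 barcodes of the E13 libraries labelled positive and negative, 4074 of 5352 of the P2 control, 3832 of 4121 of the P2 cKO, 6264 of 7561 and 6172 of 7246 at P10, and 6870 of 7780 and 7777 of 8571 at P28 (ALM, V1). Kept UMIs were 82627158 and 45515927 at E13, 16739706 and 23884677 at P2, 96806927 and 87724398 at P10, and 74402218 and 74049550 at P28. In the P2 control 1039 barcodes were over the mitochondrial limit. At most 1.10% of barcodes were shared by any of the 28 pairs of libraries.

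The libraries of each age were clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 1) without batch correction. Clusters were named from 21 marker lists fixed before the data were examined. A marker counted where its log2 level (after adding 5 CPM) lay at least 1 above background and it was detected in at least 5% of barcodes; background was the 20th percentile over clusters with at least 20 barcodes of the same library. At E13 a cluster took the name with the largest mean excess over background. After E13 names were chosen in steps. A cell type outside the interneurons was taken if its excess was above those of MGE and CGE and enough of its markers counted. Striatal, Meis2 and, at P2, subpallial types came next by a similar rule, then MGE or CGE. At P10 and P28 the class with the largest excess within MGE or CGE followed, except that Lamp5 could be chosen across both. A cluster kept its name if at least 3 of its markers counted. It stayed unnamed if a sibling class came within 0.25, if its 10 leading genes held more markers of another class, if its median depth was below that of its library by a factor of 3 or more and no leading gene was its own marker, or (after E13) if it was over 2 times as deep and carried both MGE and CGE markers. These naming rules and thresholds were revised several times after the clusters had been seen, and P2 Sst-like nuclei were named by clustering each P2 library by itself. Class names carry "-like" for this reason. Unnamed barcodes, left out of class sums, were 4.34% and 23.6% at E13, 1.50% and 13.9% at P2, 27.6% and 24.2% at P10, and 25.0% and 18.5% at P28. The tests below were run once the names were settled.

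P28 was compared with P10, and V1 with ALM, on UMIs summed per library and class (at least 20 nuclei) with edgeR 4.0.16 quasi-likelihood tests, a model of area and age, TMM scaling and filterByExpr. This left 1 residual degree of freedom, so the spread was largely shared across genes (prior degrees of freedom 12.6, 10.5 and 15.4 in Pvalb-, Sst- and Vip-like nuclei, infinite in Lamp5-like). P-values were adjusted by Benjamini-Hochberg at 0.05. Differences of an effect between classes were tested as interactions. The 26 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at a correlation of 0.01, and again with the correlation estimated. The other comparisons had 1 library per group and no test: CPM ratios of summed UMIs are given with exact 95% binomial intervals, shares with exact binomial intervals and list medians with their percentile among 10000 random lists matched on level. A fold against 0 used a floor of 3 counts. Ratios across libraries with different annotation used the genes in both.

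Genes were named by a rule written before the data were examined. Always named were Mef2c, Mef2a and Mef2d (cKO), Dlx6, Dlx6os1, Dlx5, Lhx6 and Nkx2-1 (E13), and Sst, Pvalb, Vip and Lamp5 (class levels). In tests, the 6 largest changes each way were named among genes that passed, had the same sign in both pairs and reached 20 CPM. In untested comparisons the 8 largest each way were named among genes with at least 100 UMIs in the pair of sums and 50 CPM in the higher. Members of a list with the largest changes and at least 20 CPM were named beside it. Sex-linked, mitochondrial, ribosomal, haemoglobin and unnamed-transcript genes were left out of the ranks. A few genes and 1 list result that the rule would name were not used here.

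The alternatives set before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a model without the other factor, each library left out, resolution 2, doublets kept, nuclei thinned to 3000 UMIs, fry, a minimum of 1000 genes, median-of-ratios centring, means over cells, a minimum of 400 UMIs, P2 libraries clustered singly, and ratios minus those of nuclei that were not MGE-like. Added after seeing the data were placing unnamed clusters in their closest class, ratios minus those of excitatory-like nuclei, leaving out an MGE-like cluster led by Adarb2 and Htr2c, leaving out the P2 MGE-like subclusters led by Nos1 and Npy (each library's MGE-like nuclei clustered again by themselves), and leaving out genes whose 3' end (500 bases) lies in another gene. Data for edgeR were simulated with 200 changed genes, the same spread for all genes (biological coefficient of variation 0.1) and no age-by-area interaction. On these, edgeR recovered 74.6% to 100% of genes changed 2-fold and 28.4% to 67.2% of those changed 1.5-fold, with 2.80% to 6.79% false calls. Interaction tests recovered 38.8% to 80.6% at 2-fold, with 0.962% to 7.64% false calls, over 5% in 4 of 12 cases. Far more genes passed for age in the data, and an interaction was possible there, so the simulated rates do not carry over to the calls. Counting intervals covered 95.4% to 95.6% of ratios simulated with counting error alone. Software also included Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, Matplotlib 3.10.9 and R 4.3.3.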

Results

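The series holds 8 droplet single-cell or single-nucleus RNA libraries from mouse, each made to follow GABAergic interneurons as they leave the medial ganglionic eminence (MGE), the embryonic zone that gives rise to most Pvalb and Sst interneurons, and mature in the cortex. At embryonic day 13 (E13) there was 1 library of MGE cells labelled Dlx6-positive (labelled as postmitotic cells) and 1 labelled Dlx6-negative (labelled as progenitors). At postnatal day 2 (P2) there was 1 library of sorted nuclei from whole cortex and 1 labelled as a conditional knockout (cKO) of Mef2c, a transcription factor of neuronal maturation. At P10 and P28 there was 1 library each from the cortical areas labelled ALM and V1. The deposited tables held 91580034 and 48796256 unique molecular identifiers (UMIs) in 6914 and 4362 barcodes for the E13 libraries labelled positive and negative, 20005022 UMIs in 5352 barcodes for the P2 control, 25814457 in 4121 for the P2 cKO, 108519534 in 7561 and 97991664 in 7246 for P10 ALM and V1, and 84408344 in 7780 and 85298578 in 8571 for P28 ALM and V1. After filtering, median UMIs per barcode were 12040 and 10490 at E13, 3401 in the P2 control, 5740 in the cKO, 13080 and 11880 at P10, and 8716 and 8140 at P28. Each group had 1 library, so only the crossed P10 and P28 libraries (2 ages by 2 areas) allowed a test, and intervals on single libraries cover counting error only. P-values measure only the spread among these libraries. No combination of age and area was repeated, so their error holds the age-by-area interaction together with library noise.

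The first comparison asked how MGE cells labelled Dlx6-positive and Dlx6-negative differ at E13. The library labelled Dlx6-positive held less, not more, RNA of the Dlx6 locus. Dlx6 (ENSMUSG00000029754, mm10 chromosome 6, 6863334 to 6868568, plus strand), a homeobox factor of GABAergic neurons, was at 42.6 CPM in the library labelled positive and 133 CPM in the library labelled negative, a log2 ratio of −1.64 (95% interval −1.70 to −1.58). Dlx6os1 (ENSMUSG00000090063, chromosome 6, 6820189 to 6871592, minus strand), the antisense RNA whose span contains Dlx6, was at 249 and 1380 CPM (−2.47, −2.49 to −2.45), so reads of this overlapping pair are uncertain wherever strand was not used. Dlx5 (ENSMUSG00000029755, chromosome 6, 6877805 to 6882085) was at 124 and 679 CPM (−2.46, −2.49 to −2.42), and Lhx6 (ENSMUSG00000026890, chromosome 2, 36081953 to 36105408), the factor that marks postmitotic MGE neurons, at 41.8 and 307 CPM (−2.88, −2.93 to −2.83). Nkx2-1 (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908), which specifies the MGE, was nearly level at 698 and 670 CPM (0.06, 0.04 to 0.08). These genes go against the labels, so both are called the library labelled positive or negative throughout.

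The library labelled positive carried a progenitor profile. Its 8 largest positive log2 ratios were Rgcc (5.52), the Notch effectors Hes1 (5.50) and Hes5 (4.22), the cyclin Ccnd1 (5.29), the endothelin receptor Ednrb (4.93), Suclg2 (4.74), the matrix protein Sparc (4.64) and Tcf7l2 (4.21). The 8 most negative were the peptide gene Sst (−10.35, from 5 against 3585 UMIs), Nxph1 (−6.01), the semaphorin receptor Plxna4 (−5.01), Fam65b (−4.84), the interneuron factor Maf (−4.76), Rai2 (−4.62), Actl6b (−4.55), a chromatin subunit of postmitotic neurons, and Myt1l (−4.47). All 18 measured S phase genes were higher (median 2.01, percentile 100 among 10000 matched random lists; Ung 3.42, Dtl 3.20, Mcm3 2.78), as were all 20 G2 and mitosis genes (median 0.87, percentile 100; Aurkb 1.61, Ccna2 1.42), all 10 radial glia genes (median 2.69, percentile 100; Slc1a3 4.08, Fabp7 3.45) and 9 of 11 neurogenic progenitor genes (median 1.17, percentile 100; Olig2 3.77, Gsx1 3.56). All 13 postmitotic neuron genes were lower (median −2.45, percentile 0; Syt1 −4.30, Ina −4.28, Mapt −4.20), all 10 genes of MGE cortical interneurons were lower (median −3.44, percentile 0; Erbb4 −4.26), and 5 of 7 subpallial projection genes were lower (median −1.23, percentile 0.43; Lhx8 −2.08). Genes of GABA synthesis and release were lower in 6 of 7 cases (median −1.64, percentile 0.02; Gad1 −3.82, Gad2 −3.37, Slc32a1 −3.33) and genes of migration in 18 of 19 (median −1.54, percentile 0; Robo2 −3.79, Dcx −3.07). Electron transport (7 of 14 higher, median −0.02, percentile 29.26) and axon guidance genes (15 of 24 higher, median 0.21, percentile 87.91) did not stand apart. All 5 red blood cell genes were higher (median 9.99, percentile 100; Hba-a2 10.99), and 101 of 6527 barcodes of the library labelled positive were red blood cell-like, against 3 of 4208.

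Cell classes differed the same way. Radial glia-like cells made up 57.8% (56.6 to 59.0) of the library labelled positive and 0.499% (0.309 to 0.762) of the library labelled negative, whereas MGE neurons of cortical interneuron type made up 0.444% (0.298 to 0.638) and 35.2% (33.7 to 36.6). Intermediate progenitor-like cells were present in both, at 30.7% and 22.7%. Within these 2004 and 957 cells the library labelled positive again had the lower log2 ratios of Dlx6 (−0.40), Dlx6os1 (−0.94), Dlx5 (−1.19) and Lhx6 (−1.65), and higher Ccnd1 (4.16), Gsx1 (3.32), the cell cycle kinase Cdk6 (3.01) and Olig2 (2.70). Within the subpallial projection type (304 and 512 cells) Dlx6 was higher in the library labelled positive (0.61, 0.39 to 0.82), while Dlx5 (−0.52), Dlx6os1 (−0.63) and Lhx6 (−1.16) were lower. Cells of this type also differed in progenitor genes between the libraries, so these ratios may not compare like cells. With 1 library per label these differences had no replicate check, and 10 of the 17 E13 clusters took over 90% of their cells from 1 library.

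**Figure D1:**
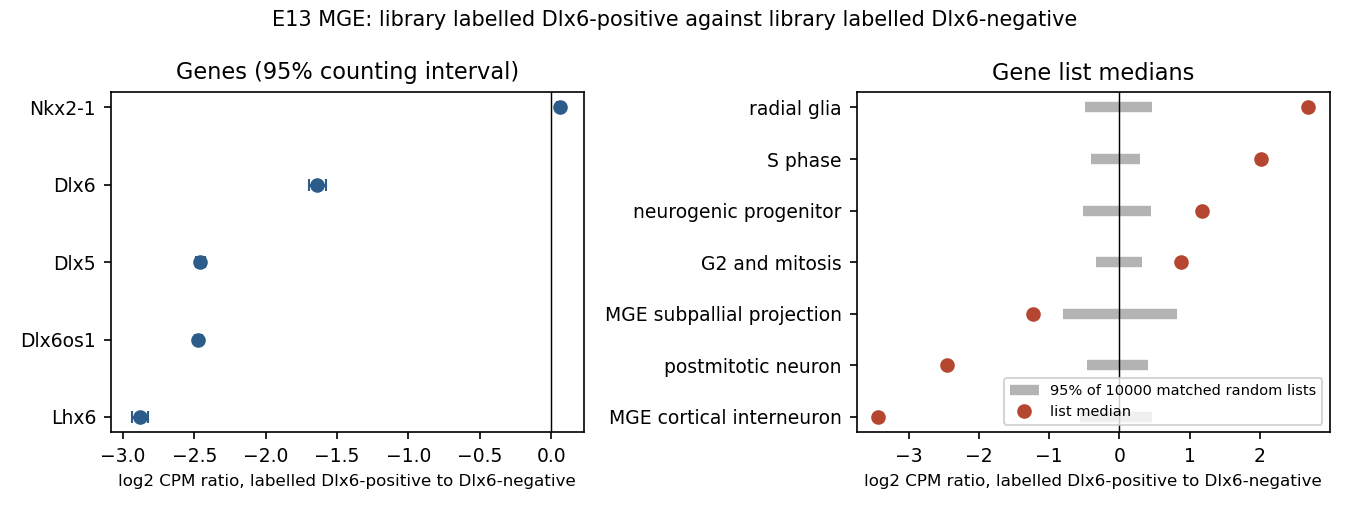
E13 log2 CPM ratios, library labelled Dlx6-positive to library labelled Dlx6-negative (x axis, log2). Left, genes with 95% counting intervals, from Lhx6 at −2.88 to Nkx2-1 at 0.06; right, medians of 7 gene lists (points) over the 95% range of 10000 matched random lists (grey bars), from −3.44 for MGE cortical interneuron genes to 2.69 for radial glia genes.

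The share of each interneuron class was compared across ages and areas. Pvalb-like nuclei made up 25.3% (24.2 to 26.4) of P10 ALM, 31.3% (30.1 to 32.5) of P10 V1, 29.7% (28.7 to 30.8) of P28 ALM and 31.0% (30.0 to 32.1) of P28 V1. The P10 gap between areas was not stable. With doublets kept, Pvalb-like nuclei were 1670 of 6614 in P10 ALM and 1638 of 6511 in P10 V1, nearly the same share. At resolution 2 the gap stayed (1448 of 6264 and 1702 of 6172). Sst-like nuclei made up 27.0% and 28.4% at P10 and 14.6% and 14.7% at P28 (ALM, V1). Vip-like nuclei made up 6.94% and 5.43% at P10 and 7.25% and 9.21% at P28, and Lamp5-like nuclei 7.81% and 6.37% at P10 and 11.6% and 10.5% at P28. Excitatory-like nuclei made up 1.63% and 2.04% at P10 but 7.55% and 11.1% at P28, although all 4 libraries were sorted for the interneuron reporter. With a minimum of 1000 genes per nucleus the P28 excitatory-like shares were 4.92% and 6.81%. Unnamed nuclei made up 27.6% and 24.2% at P10 and 25.0% and 18.5% at P28, enough to set part of these differences. With 1 library per age and area no test was made. The sort, the shallower P28 libraries and the class boundaries can each set a share.

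At P2 the control held 45.6% MGE-like (1856 nuclei), 28.9% CGE-like and 13.1% Meis2-like nuclei, CGE being the caudal eminence that gives rise to Vip and Lamp5 interneurons. The cKO library, labelled as MGE-derived, held 55.3% MGE-like (2120 nuclei), 0.0783% CGE-like, 16.8% of an MGE subpallial projection type and 13.5% excitatory-like nuclei.

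**Figure D2:**
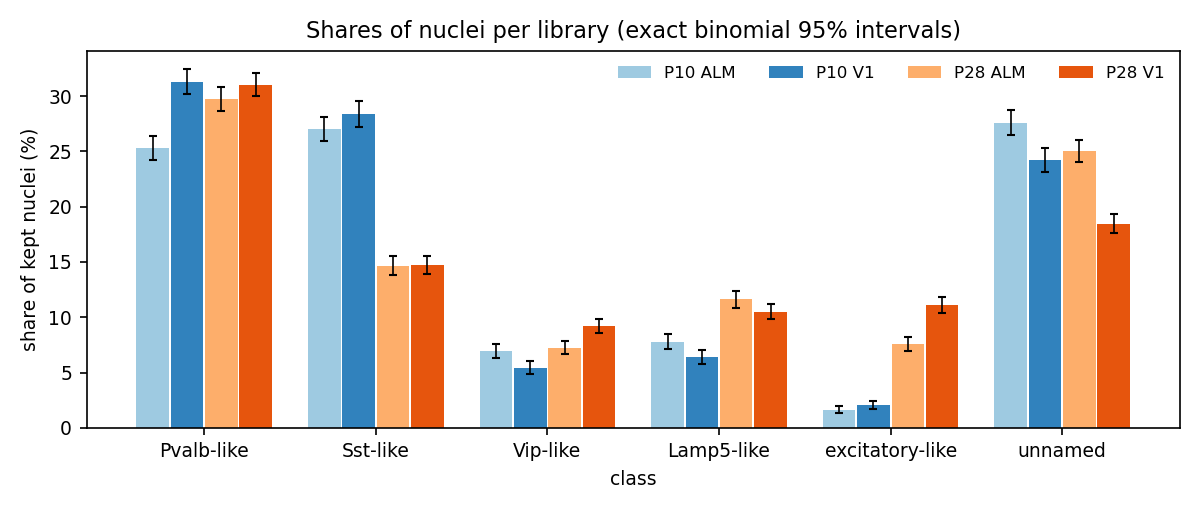
Share of kept nuclei (y axis, %) by class (x axis) in P10 ALM, P10 V1, P28 ALM and P28 V1, with exact binomial 95% intervals; each bar is 1 library. Sst-like shares were 27.0% and 28.4% at P10 and 14.6% and 14.7% at P28, and excitatory-like shares 1.63% and 2.04% at P10 and 7.55% and 11.1% at P28.

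How each class matured between P10 and P28 was tested across the 4 libraries (n = 2 per age, from different areas). In Pvalb-like nuclei the largest rise was Pvalb itself (ENSMUSG00000005716, chromosome 15, 78191114 to 78206400), the calcium buffer that names the class, with a log2 fold change of 5.07 ± 0.12 (SE; edgeR adjusted p = 1.45e-11), from 2.19 to 73.6 CPM. It was followed by the secreted matrix protein Adamtsl5 (4.73 ± 0.13), the sphingosine phosphate phosphatase Sgpp2 (3.47 ± 0.15), Bcan (2.99 ± 0.13), a proteoglycan of perineuronal nets, the TGF-beta receptor Tgfbr2 (2.67 ± 0.16) and Ypel4 (2.65 ± 0.15). The largest falls were Tg (−4.84 ± 0.15), the AMPA receptor auxiliary subunit Cacng4 (−4.40 ± 0.15), the cation channel Trpc7 (−4.13 ± 0.17), the adaptor Sla (−3.88 ± 0.21), the secreted Fam19a1 (−3.77 ± 0.17) and the relaxin receptor Rxfp1 (−3.62 ± 0.14). All 12 had an adjusted p of 8.66e-09 or less. Sla lies inside Tg on the opposite strand of chromosome 15, so their reads are uncertain. In all, 10784 of 17610 genes passed (5482 up, 5302 down), 1977 and 2194 of them by at least 2-fold.

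In Sst-like nuclei, Sst (ENSMUSG00000004366, chromosome 16, 23889573 to 23890958) rose by 1.76 ± 0.10 (adjusted p = 3.06e-07), from 61.6 to 202 CPM. The largest rises were the vomeronasal receptor Vmn2r30 (2.67), the immediate early factor Junb (2.43), the transporter Slc16a11 (2.43), the nuclear noncoding RNA Malat1 (2.27), Runx2os1 (2.26) and Resp18 (2.18). The largest falls were Tg (−3.45), Ppfibp1 (−3.22), the TGF-beta binding protein Ltbp1 (−3.20), the repressor Bcl6 (−2.85), the sialyltransferase St6galnac5 (−2.74) and Gxylt2 (−2.49). These 12 had standard errors of 0.08 to 0.26 and adjusted p of 1.65e-06 or less. In all, 9246 of 16793 genes passed (4685 up, 4561 down).

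In Vip-like nuclei the immediate early gene Fos rose by 4.26 ± 0.39 (edgeR adjusted p = 3.76e-07), Junb by 3.62 ± 0.24, Ier2 by 3.23 ± 0.44 and Egr1 by 3.20 ± 0.35, beside Akain1 (3.19 ± 0.20) and the phospholipase Plce1 (3.15 ± 0.23). Fos, Junb, Ier2 and Egr1 rose less in ALM (2.89, 2.84, 2.00 and 1.90) than in V1 (5.41, 4.12, 5.48 and 4.48). Their P10 means were low, at 1.19 to 4.54 CPM. The peptide gene Vip (ENSMUSG00000019772, chromosome 10, 5639218 to 5647617) rose by 1.30 ± 0.10, from 227 to 564 CPM. The receptor Pth2r (−3.09), the polysialyltransferase St8sia2 (−2.93), the collagen Col9a2 (−2.66), the immature tubulin Tubb2b (−2.53), the potassium channel Kcnh8 (−2.52) and Nnat (−2.39) fell most. In all, 5512 of 13074 genes passed (2719 up, 2793 down).

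In Lamp5-like nuclei the largest rises included Fam19a1 (4.55 ± 0.11), Teddm3 (4.42), the prolyl hydroxylase Egln3 (3.73), the vesicular glutamate transporter Slc17a7 (3.66) and the sorting receptor Sorcs1 (3.0). Slc17a7 is an excitatory neuron gene, and the excitatory-like share was also higher in the P28 libraries. The largest falls were the prolactin receptor Prlr (−5.31 ± 0.24), whose 3' end lies inside the gene Gm21973 on the same strand and whose reads are uncertain, the Wnt antagonist Dkk2 (−3.85), the anion transporter Slc26a7 (−3.80), the perinatal myosin Myh8 (−3.56), Abca8a (−3.44) and Zfp521 (−3.38). Lamp5 itself (ENSMUSG00000027270, chromosome 2, 136052239 to 136069917) fell by 0.42 on the log2 scale (adjusted p = 1.64e-05), from 193 to 145 CPM. In all, 7035 of 14537 genes passed (3543 up, 3492 down). P-values of this class were extreme (Dkk2 adjusted p = 9.63e-184) because its fit took the same spread for all genes.

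Mef2c fell in Pvalb-like (−0.84 ± 0.10), Sst-like (−0.30 ± 0.07) and Lamp5-like nuclei (−0.63 ± 0.09), and its change in Vip-like nuclei did not pass (−0.06 ± 0.08, adjusted p = 0.561). Pvalb, Vip and Sst also rose outside their own class, while Lamp5 did not pass in Pvalb-like (0.03, adjusted p = 0.915), Sst-like (0.38, 0.190) or Vip-like nuclei (−0.02, 0.961). Pvalb rose by 4.19 in Sst-like and 3.86 in Vip-like nuclei, reaching 9.47 and 9.01 CPM at P28, and in Lamp5-like nuclei from no UMI at P10 to 7.87 CPM. Vip rose by 1.45, 1.58 and 1.76 in Pvalb-, Sst- and Lamp5-like nuclei, and Sst by 0.81, 1.01 and 0.88 in Pvalb-, Vip- and Lamp5-like nuclei. Both were also higher at P28 in nuclei that should lack them. In excitatory-like nuclei Vip went from 9.80 to 33.8 CPM in ALM and 9.84 to 25.2 in V1, and Sst from 17.7 to 31.2 and 7.66 to 16.9. In oligodendrocyte-like nuclei Vip went from 17.8 to 203 and 25.3 to 98.3 CPM, and Sst from 30.1 to 83.2 and 16.9 to 78.6. Free RNA may therefore be part of these rises. Malat1, a nuclear RNA that can track RNA quality, took 2.89% and 2.68% of UMIs at P10 and 13.3% and 12.1% at P28.

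Genes of axon guidance and adhesion fell in every class. Camera took no account of gene length, here or for the lists below. Whether the age changes followed length was not tested, so length was not separated from list membership. In Pvalb-like nuclei 28 of 29 fell and 1 rose (median −1.07, camera adjusted p = 4.17e-08; Cdh8 −2.20, Epha3 −2.06, Sema6a −1.85, Dcc −1.81). In Sst-like nuclei 27 of 29 fell and 0 rose (median −0.88, adjusted p = 4.85e-07; Slit2 −2.39, Dcc −2.03, Epha7 −1.51). In Vip-like nuclei 21 fell and 5 rose (median −0.74, adjusted p = 0.00277; Slit2 −1.57, Cdh9 −1.27), and in Lamp5-like nuclei 23 fell and 5 rose (median −0.88, adjusted p = 0.000682; Pcdh15 −2.52, Slit3 2.69, Ntng1 1.79). Adjusted over the list alone the counts were the same, except that 6 rose in Vip-like nuclei. Migration and immaturity genes fell in Pvalb-like (12 of 18, median −0.85, adjusted p = 0.0304; Sox11 −2.75), Vip-like (11 of 15, 12 adjusted over the list alone, median −0.82, adjusted p = 0.00277; Sox11 −2.04) and Lamp5-like nuclei (12 of 16, median −0.69, adjusted p = 0.00344; Nrp2 −1.60, Plxna4 −1.57), while in Sst-like nuclei 9 of 16 fell and the list did not pass (median −0.73, adjusted p = 0.0810). Postmitotic neuron genes, the list used at E13, fell in Pvalb-like (10 of 12, median −0.89, adjusted p = 0.0167; Gap43 −2.81, Stmn2 −1.48), Vip-like (8 of 12, median −0.58, adjusted p = 0.0496) and Lamp5-like nuclei (8 of 12, median −0.56, adjusted p = 0.0238), and did not pass in Sst-like nuclei (9 of 12, median −0.63, adjusted p = 0.0740). With an estimated correlation, which rests on 1 residual degree of freedom, these lists had adjusted p = 0.715 in Pvalb-like, 0.744 in Sst-like (axon guidance), 0.83 in Vip-like and 0.69 in Lamp5-like nuclei.

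Nuclear-encoded genes of electron transport rose in every class. In Pvalb-like nuclei 12 of 13 rose (median 0.99, adjusted p = 0.00487; Cycs 1.5, Atp5a1 1.26, Cox7c 1.15), in Sst-like 11 of 13 (0.85, 0.00326; Cox7c 1.30), in Vip-like 8 of 13 (0.70, 0.00527; 9 adjusted over the list alone) and in Lamp5-like 8 of 13 (0.82, 0.0238), and 0 fell. Neuropeptide and calcium-binding protein genes rose in 7 of 13 cases in Pvalb-like (median 0.81, adjusted p = 0.0247; Npy 2.34, Tac1 2.08), 8 of 13 in Sst-like (0.72, 0.0281; Npy 2.01), 9 of 12 in Vip-like (1.12, 0.0028; Npy 2.55, Cck 2.09, Penk 1.06) and 8 of 12 in Lamp5-like nuclei (1.37, 0.0417; Npy 1.73, Cck 1.45). With an estimated correlation both lists had adjusted p = 0.715, 0.744, 0.83 and 0.69 in Pvalb-, Sst-, Vip- and Lamp5-like nuclei. Npy was also higher at P28 in excitatory-like nuclei (4.20 to 41.9 CPM in ALM, 7.66 to 23.9 in V1) and oligodendrocyte-like nuclei (15 to 194, 11.8 to 80.8). In excitatory-like nuclei Cck (17.3 to 40.0 and 8.20 to 32.0 CPM) and Tac1 (1.87 to 8.02 and 0.547 to 3.91) were higher at P28 too, so part of these rises may not belong to the class.

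Receptor and channel genes mostly fell. Glutamate receptor subunits fell in Pvalb-like (11 of 15, median −0.64, adjusted p = 0.0247; Grin3a −2.51, Grik1 −1.65, Gria1 −1.59), Sst-like (11 of 14, −0.62, 0.00951; Grik1 −1.71) and Vip-like nuclei (10 of 14, −0.50, 0.0496; Grik1 −2.06, but Gria3 rose by 1.23); in Lamp5-like nuclei 8 of 14 fell and the list did not pass (−0.42, 0.0848). GABA-A receptor subunits fell in Sst-like (9 of 12, −0.51, 0.0285; Gabra5 −1.67, Gabrg3 −1.29) and Lamp5-like nuclei (10 of 12, −0.57, 0.00322; Gabra2 −1.25); the list did not pass in Pvalb-like (8 of 12 fell, −1.0, 0.0575) or Vip-like nuclei (8 of 12, −0.51, 0.134). Potassium channels split in Pvalb-like nuclei: 13 of 20 fell (median −0.73, adjusted p = 0.0329; Kcnq5 −1.97, Kcnb2 −1.97), while Kcna1 (2.26) and Kcnc1 (2.16), subunits of fast-spiking neurons, rose. In Sst-like nuclei 14 of 20 fell (−0.52, 0.0359; Kcnip4 −2.20, Kcnq5 −1.81) and Kcna1 (1.58) and Kcna2 (1.38) rose. Sodium and calcium channels fell in Pvalb-like (13 of 17, −0.58, 0.0167; Cacna1g −3.23, Scn3a −2.03) and Sst-like nuclei (13 of 17, 14 adjusted over the list alone, −0.45, 0.00951; Cacna1i −1.26, but Scn2b rose by 1.00). Neither channel list passed in Vip-like (potassium −0.23, 0.133; sodium and calcium −0.17, 0.334) or Lamp5-like nuclei (−0.17, 0.284; −0.26, 0.106). In Pvalb-like nuclei interneuron transcription factors (16 of 26 fell, 18 adjusted over the list alone, −0.51, 0.0247; Npas3 −1.24, Mef2a −1.20) and astrocyte RNA (3 of 6 fell, −0.80, 0.0393) also passed. The lists of this paragraph that passed had adjusted p = 0.715 in Pvalb-like (0.766 for potassium channels and astrocyte RNA), 0.744 in Sst-like, 0.83 in Vip-like and 0.69 in Lamp5-like nuclei with an estimated correlation.

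In Lamp5-like nuclei activity-regulated genes rose (9 of 11, 10 adjusted over the list alone, median 2.56, camera adjusted p = 0.000682; Junb 2.48), with adjusted p = 0.69 with an estimated correlation. Activity-regulated genes had positive medians in the other classes without passing (0.77, adjusted p = 0.205 in Pvalb-like; 0.96, 0.485 in Sst-like; 1.65, 0.134 in Vip-like). Differences of list results between classes were not tested. No list call for age held with an estimated correlation. The age effect held across genes between areas, with a correlation across genes of the ALM and V1 differences of 0.88, 0.83, 0.78 and 0.79 in Pvalb-, Sst-, Vip- and Lamp5-like nuclei (genes are not independent replicates). A DESeq2 Wald test called 6849, 4937, 1724 and 2494 genes.

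**Figure D3:**
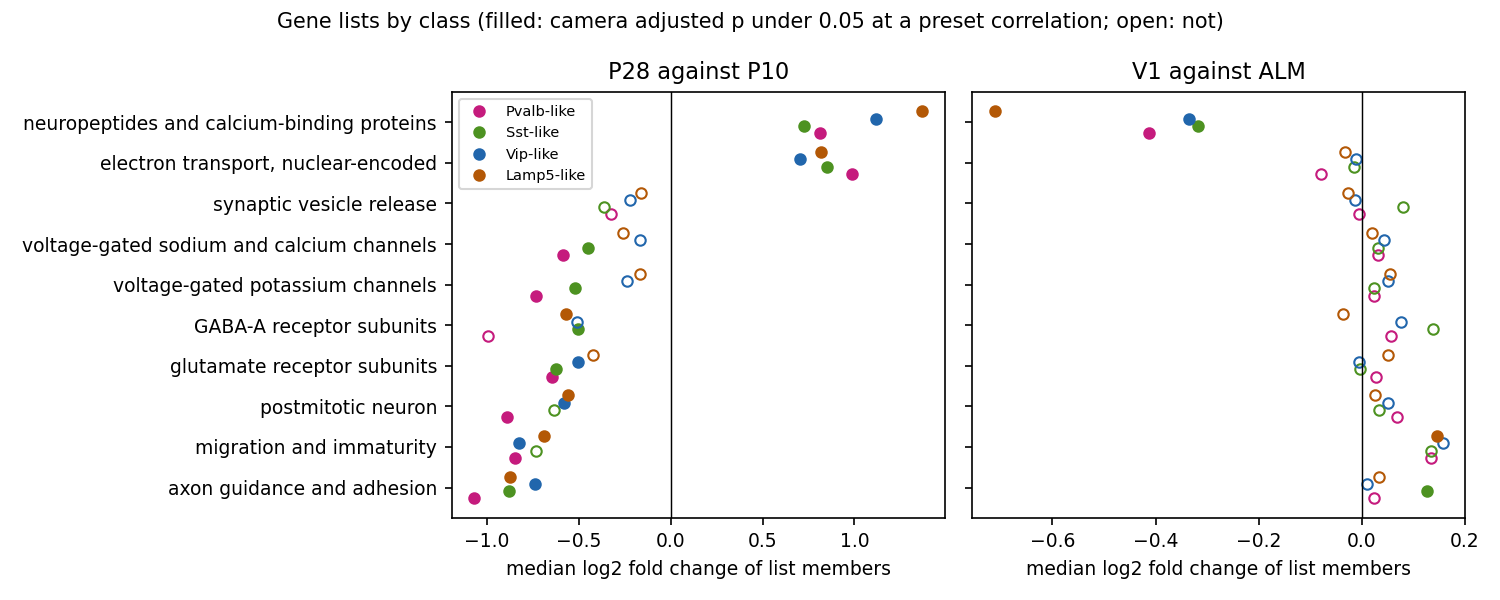
Median log2 fold change of the members of 10 gene lists (x axis) in Pvalb-, Sst-, Vip- and Lamp5-like nuclei, for P28 against P10 (left) and V1 against ALM (right); filled points have a camera adjusted p under 0.05 at a preset correlation. Axon guidance genes lie at −1.07 to −0.74 in the age panel, and neuropeptide genes at −0.71 to −0.32 in the area panel.

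V1 was compared with ALM in the same 4 libraries (n = 2 per area, from different ages and so not replicates of the same condition). Several peptide genes were lower in V1. In Pvalb-like nuclei the substance P precursor Tac1 fell by 1.39 ± 0.15 on the log2 scale (edgeR adjusted p = 0.00029), Cck (cholecystokinin) by 1.18 ± 0.14 (0.000422) and Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), neuropeptide Y, by 1.03 ± 0.13 (0.000659). Npy also fell in Vip-like nuclei (−0.91 ± 0.15, 0.0211) and Lamp5-like nuclei (−1.08 ± 0.10, 5.95e-25), and Sst fell in Pvalb-like (−0.66), Sst-like (−0.64) and Lamp5-like nuclei (−0.77) but did not pass in Vip-like nuclei (−0.69, adjusted p = 0.162). Vip did not pass in Pvalb-like (−0.32, adjusted p = 0.536), Sst-like (−0.48, 0.304) or Vip-like nuclei (−0.27, 0.630). The neuropeptide list was lower in each class: in Pvalb-like nuclei 4 of 13 fell (5 adjusted over the list alone; median −0.41, camera adjusted p = 0.00219), in Sst-like 4 of 13 (5 down and 1 up; −0.32, 0.0044), in Vip-like 1 of 12 (6 down and 1 up; −0.33, 0.0128) and in Lamp5-like 6 of 12 (7; −0.71, 4.23e-05). With an estimated correlation these were adjusted p = 0.84, 0.837, 0.993 and 0.875. Peptide RNA was also lower in V1 in excitatory-like nuclei: Sst, Npy and Vip together were at 107 CPM in ALM and 66.0 in V1 at P28 (log2 ratio −0.70, −0.85 to −0.55), and at 31.7 and 25.2 CPM at P10 (−0.34, −0.91 to 0.23). So was Sst alone at P10 (−1.21, −2.21 to −0.29) and P28 (−0.88, −1.17 to −0.59). So were Tac1 at P28 (−1.04, −1.65 to −0.44) and Cck at P10 (−1.07, −2.05 to −0.17) and P28 (−0.32, −0.55 to −0.09). Tac1 was also lower in V1 in Sst-like (−1.42 at P10, −1.32 at P28) and Vip-like nuclei (−1.74, −1.23). In CPM, Tac1 fell by 13.6 and 36.5 in Pvalb-like (P10, P28), 1.32 and 4.11 in excitatory-like and 4.74 and 10.9 in Vip-like nuclei. Oligodendrocyte-like nuclei held 2 and 5 Tac1 UMIs at P28, too few to compare. The CPM falls argue against free RNA as the whole Tac1 fall, but not as a part. The Cck fall at P28 was 16.1 CPM in Pvalb-like and 23.6 in Vip-like nuclei, so free RNA was not excluded for Cck. The Npy fall at P28 was 53.3 CPM in Pvalb-like and 64.8 in Vip-like nuclei. Both exceeded the fall in excitatory-like nuclei but not the 113 CPM in oligodendrocyte-like nuclei (31 in ALM, 138 in V1). Free RNA was therefore not excluded for Npy in Pvalb- and Vip-like nuclei.

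Other genes passed for area within each class, and Banf2 passed in both Pvalb- and Sst-like nuclei. Pvalb-like nuclei had higher Banf2 (1.42 ± 0.09, edgeR adjusted p = 4.61e-06), Fam19a1 (1.39), the adhesion protein Tenm2 (1.23), the heparan sulfate sulfotransferase Hs6st3 (1.07), the channel Trpm3 (1.07) and the T-type calcium channel Cacna1i (1.07) in V1, and lower Gulp1 (−1.31), Ltbp1 (−1.13) and the protease Prss23 (−1.03). Sst-like nuclei had higher angiopoietin 1 (Angpt1, 2.09 ± 0.24, adjusted p = 0.000744), the serotonin receptor Htr7 (1.59), Banf2 (1.40), Ppfibp1 (1.39), autotaxin (Enpp2, 1.36) and Fmn1 (1.36) in V1. They had lower BMP receptor Bmpr1b (ENSMUSG00000052430, chromosome 3, 141837136 to 142169425; −2.42 ± 0.19, 7.1e-05), Adgrl2 (−1.69), Ets1 (−1.46), Tgfbr1 (−1.32), Pld5 (−1.14) and AC159282.1 (−1.09). Mef2c was higher in V1 in Sst-like nuclei (0.43 ± 0.07, 0.00988). In Vip-like nuclei 7 genes passed: Junb (1.44) and Sntb1 (1.00) were higher, and Frem1 (−1.42), the receptor kinase Alk (−1.09), Npy, Pde1c (−0.85) and Opcml (−0.48) lower. Lamp5-like nuclei had higher glutamate transporter Slc1a3 (1.35), Tenm3 (1.32), the nitric oxide synthase Nos1 (1.13), Abca8a (1.11), the semaphorin receptor Nrp2 (0.98) and Pard3bos1 (0.96), and lower Ism1 (−1.89), Prr16 (−1.14), Adamts6 (−0.84), Mrpl45 (−0.80), Cck (−0.79) and Vip (−0.65). Vip differed in sign between the ages (0.26 at P10, −0.99 at P28), so its area effect was not shared by both. Others kept their sign but rested mostly on a single age. Trpm3 was at 1.63 at P10 and 0.09 at P28, Gulp1 at −2.00 and −0.45, and Ppfibp1 at 1.54 and 0.40. Abca8a was at 1.30 and 0.28, Pard3bos1 at 1.17 and 0.23, and Junb in Vip-like nuclei at 0.30 and 1.59. Banf2 in Pvalb-like nuclei was similar at both ages (1.47 and 1.37).

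Of the remaining lists, axon guidance was higher in V1 in Sst-like nuclei (5 of 29 rose and 1 fell, 13 and 3 adjusted over the list alone; median 0.13, camera adjusted p = 0.0468; Slit2 0.88, Slit3 0.78, Sema6a 0.52), and excitatory neuron RNA was lower there with 0 of 5 members passing (−0.58, 0.0468). In Lamp5-like nuclei activity-regulated genes (4 of 11 rose, 0.53, 0.0177; Junb 0.81), migration genes (2 of 16, 5 adjusted over the list alone, 0.15, 0.0177; Nrp2 0.98, Nrp1 0.94) and perineuronal net genes (1 of 9, 0.20, 0.0177; Hapln1 0.45) were higher. With an estimated correlation these had adjusted p = 0.837 in Sst-like and 0.875 in Lamp5-like nuclei. In all, 314 genes passed in Pvalb-like (177 up, 137 down), 417 in Sst-like (228 up, 189 down), 7 in Vip-like (2 up, 5 down; 24 up and 18 down with DESeq2 size factors) and 243 in Lamp5-like nuclei (116 up, 127 down).

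The area calls needed age in the model. Across genes, the area differences at P10 and P28 correlated weakly (0.19, 0.23, 0.05 and 0.10 in Pvalb-, Sst-, Vip- and Lamp5-like nuclei), and 219 of the 243 genes that passed in Lamp5-like nuclei had the same sign at both ages. Without any 1 library, and so without age in the model, edgeR called 0 genes in Pvalb- and Lamp5-like, 0 to 11 in Sst-like and 0 to 6 in Vip-like nuclei, with 30 to 250, 133 to 249, 83 to 410 and 125 to 235 genes at an unadjusted p under 0.05 (Pvalb, Lamp5, Sst, Vip). With all 4 libraries and no age in the model edgeR also called 0 in every class (30, 26, 101 and 7 at an unadjusted p under 0.05), so the loss cannot be put down to the library left out. With all 4 libraries and age in the model DESeq2 called 118, 14, 149 and 1. Some P10 clusters of a class came mostly from 1 area: Pvalb-like clusters led by Vit (21 nuclei in ALM, 818 in V1), Mybpc1 (733 and 100) and Tll1 (0 and 91), and an Sst-like cluster led by Hpse (11 and 646), so area and cluster were not separated in these classes. Clusters were made without batch correction, and area was not refitted without them.

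The P2 cKO library was compared with the P2 control within MGE-like nuclei. Mef2c (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080, plus strand) was at 1632 CPM in the cKO and 4196 CPM in the control, a log2 ratio of −1.36 (−1.39 to −1.34). The ratio was −1.40 in Sst-like nuclei (872 and 630) and −1.38 in the other MGE-like nuclei (1248 and 1226). Over all kept barcodes Mef2c was at 4.53 and 23.9 CPM in the E13 libraries labelled positive and negative, 2583 in the P2 control, 1478 in the P2 cKO, 1402 and 1668 at P10, and 1102 and 1156 at P28 (ALM, V1). Mef2c was also lower in excitatory-like nuclei of the cKO (−0.52, −0.58 to −0.46), leaving a difference of −0.85 between MGE-like and excitatory-like nuclei. The deleted exon and the Cre driver are not given in the sources used here, so 3' tags outside the deleted part check nothing. The related factors Mef2a (0.41) and Mef2d (0.57) were higher in the MGE-like nuclei of the cKO, but relative to excitatory-like nuclei they were at −0.52 and −0.03.

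**Figure D4:**
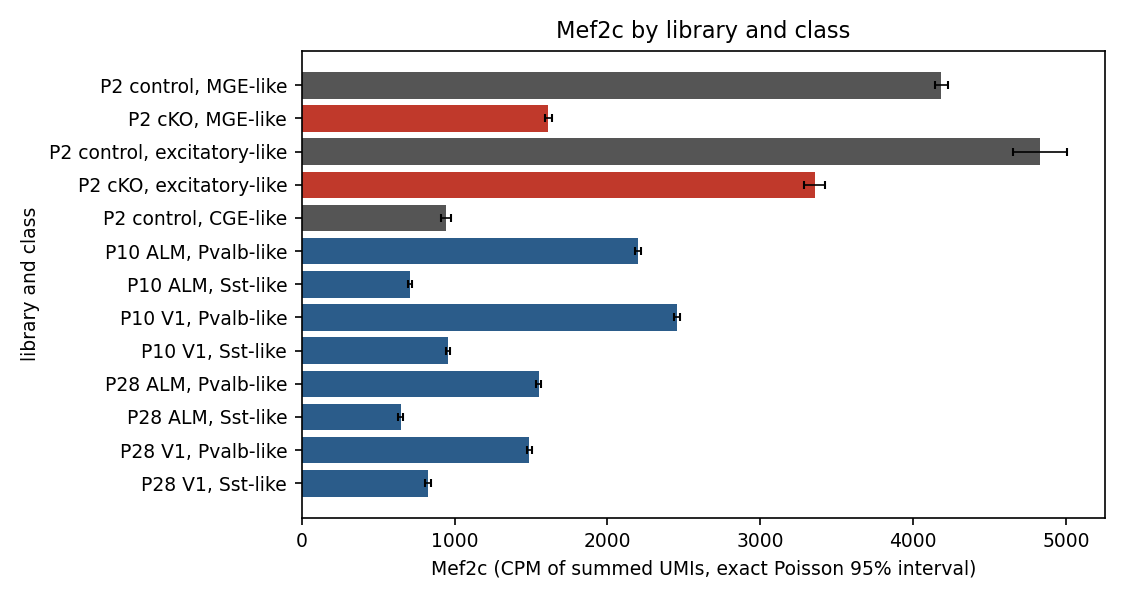
Mef2c level (x axis, CPM of summed UMIs over all genes, exact Poisson 95% intervals) by library and class (y axis); each bar is 1 library. MGE-like nuclei were at 4184 CPM in the P2 control and 1613 in the P2 cKO, and excitatory-like nuclei at 4826 and 3355.

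Many genes differed widely between these libraries: 4255 were at least 2-fold higher and 3017 at least 2-fold lower in the cKO among 11335 genes, around a median log2 ratio of 0.23. The largest positive ratios were Hs6st3 (11.69, 9.21 to 16.99, from 5095 against 1 UMI), the serotonin receptor Htr1f (11.31), Sgcz (10.52), Nrg3os (at least 1401-fold higher), Kctd16 (10.19), Rtl4 (10.18), Chsy3 (10.10) and Spag5 (at least 1006-fold higher). The largest negative were the tubulins Tuba1a (−16.76, −22.07 to −14.29, from 1 against 72172 UMIs) and Tubb3 (at least 8918-fold lower), the cytochrome oxidase subunit Cox4i1 (at least 5019-fold lower), Gnb2 (−11.88), Chchd2 (at least 3642-fold lower), Nme1 (−11.48), Map1lc3b (at least 1933-fold lower) and the complex I subunit Ndufa13 (at least 1816-fold lower). The 3' ends of these 8 lie inside another gene of the same strand. Axon guidance genes were higher in 28 of 29 cases (median 3.62, percentile 100; Dcc 8.65, Epha6 8.65), as were 16 of 18 potassium channels (2.93, 99.94), all 14 glutamate receptor subunits (2.66, 98.96), all 17 sodium and calcium channels (2.41, 99.49) and 10 of 12 GABA-A receptor subunits (2.28, 99.38). Electron transport genes were lower in 13 of 14 cases (−2.49, percentile 1.70), migration genes in 13 of 20 (−1.70, 1.21) and neurogenic progenitor genes in all 5 (−2.23, 0.18). Genes of MGE cortical interneurons (6 of 10 lower, −1.05, percentile 39.22) and interneuron transcription factors (13 of 25 lower, −0.47, 35.45) did not stand apart. The random lists were matched on level but not on gene length. The ratios of this comparison rose with length (rho 0.61 over 11326 genes), so these percentiles do not separate list membership from gene length.

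The excitatory-like nuclei of these libraries differed in the same way (Spearman rho 0.897 across 10651 genes, which are not independent replicates), so ratios were also taken relative to other nuclei. Relative to the nuclei that were not MGE-like, the largest positive differences were Nr2f2 (4.95), Htr1f (4.94), Trpc6 (4.23), Grm8 (4.19), Myo10 (4.02), Serpine2 (3.92), the cannabinoid receptor Cnr1 (3.73) and Fabp7 (3.66), and the largest negative were the calcium channel subunit Cacna2d2 (−3.85), the potassium channel subunits Kcnip2 (−3.72) and Kcnj6 (−3.02), Me3 (−3.49), Sst (−3.31), Tgfb2 (−3.23), the cadherin Cdh7 (−3.13) and Bet1l (−3.0), whose 3' end lies inside Gm45785 on the same strand, so its reads are uncertain. The nuclei that were not MGE-like included 1179 CGE-like and 534 Meis2-like nuclei in the control but 3 and 2 in the cKO. Relative to excitatory-like nuclei, a reference chosen after the data were seen and absent from the control with doublets kept (0 of 4216 nuclei, against 105 of 4074), Sst (−3.53) and Kcnip2 (−3.85) were also negative, while Nr2f2 (0.23), Fabp7 (−1.81), Cdh7 (0.15) and Kcnj6 (−0.06) lost or turned their direction, and Cacna2d2 (−0.40) and Cnr1 (0.74) shrank. Sst itself was at 545 CPM in the cKO and 1335 in the control (−1.29), but this rested on 1 control subcluster of 75 nuclei at 19490 CPM, led by Nos1 and Npy, while the other control subclusters lay at 21.1 to 1064 CPM. The cKO subcluster led by Nos1 and Npy (95 nuclei) was lower, at 2653 CPM, and the other cKO subclusters lay at 229 to 771 CPM. Without the subclusters led by Nos1 and Npy (75 nuclei of the control, 95 of the cKO), left out after the result was seen, Sst was at 461 and 394 CPM (0.23, 0.16 to 0.29), and at −2.01 relative to excitatory-like nuclei. In excitatory-like nuclei Sst was itself higher in the cKO (2.24, from 534 against 25 UMIs). This reference therefore sets part of the −3.53 and turns 0.23 into −2.01. With 1 library each, none of this had a replicate check, 23 of the 25 P2 clusters took over 90% of their nuclei from 1 library, and the control library also differed in ribosomal protein RNA (10.4% of UMIs, against 0.755% in the cKO) and mitochondrial RNA (median 3.78% and 0.456%).

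From P2 to P10, each P10 area was set against the P2 control within class. In MGE-like nuclei Sst was at 1335 CPM at P2 and at 50.9 CPM in P10 ALM and 28.2 in P10 V1 (log2 ratios −4.71 and −5.56). Without the P2 subcluster led by Nos1 and Npy, P2 was at 394 CPM and the ratios were −2.95 and −3.80, so 75 nuclei set part of this difference. Mef2c was at 4196 CPM at P2 against 1462 and 1765 (−1.52 and −1.25). Pvalb was higher at P10 (2.51, 0.60 to 5.59 in ALM; 2.26, 0.34 to 5.34 in V1), from 2 UMIs at P2. In CGE-like nuclei Vip was at 523 CPM at P2 and 103 and 97.1 at P10 (−2.35 and −2.43), while Lamp5 was at 8.21 CPM at P2 and 104 and 110 CPM at P10 (3.66 and 3.75), and Mef2c was nearly level (−0.05 and −0.03). In MGE-like nuclei of ALM the largest positive ratios were Hs6st3 (12.59), Kctd16 (11.70), Nrg3os (at least 2569-fold higher), the growth factor Fgf1 (10.83), Il1rapl2 (10.62), Chsy3 (10.56), Sorbs2os (10.53) and Ctnna3 (at least 1330-fold higher); the most negative were the 8 genes that were also most negative in the cKO, with Tuba1a at 0 UMIs in P10 against 72172 (at least 139147-fold lower). Axon guidance genes were higher in 28 of 29 cases (median 3.64 in ALM, 3.56 in V1) and electron transport genes lower in 13 of 14 (−4.81, −4.88), as between the cKO and control libraries. The median over all genes was 0.13 and 0.07 in MGE-like and −0.13 and −0.22 in CGE-like nuclei (ALM, V1). These ratios have no replicate check, and the P2 control differed from the P10 libraries in whole cortex against area, in annotation and in the same gene-body pattern as from the cKO.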

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

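The tests of the E13 pattern (for scaling the prediction only, since the median-of-ratios centring was set before the data were examined), the overlap test of the P2 pattern, the test of counting as the cause of lower Mef2c and the reference to excitatory-like nuclei were chosen only after the result was seen; the tests of cytoplasmic RNA, of Mef2c loss as the cause of the wide shift and of free RNA were written before. For cytoplasmic RNA and for the peptides in excitatory-like nuclei, an interval was added to the rule after the value had been seen, because a point value alone ignored its spread. For Npy, the plain ratio of falls was replaced by a ratio to an upper bound after the value had been seen, because the fall in excitatory-like nuclei was negative at P10, and the comparison with oligodendrocyte-like nuclei was added after the result was seen. For the exchange of labels, a first test on the genes of the pattern itself could not have failed, and the share of radial glia-like cells replaced it after that share had been seen.

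A test of the difference between classes flagged age effects that were not shared. Between Pvalb- and Sst-like nuclei 3169 genes differed, between Pvalb- and Vip-like 2250, Pvalb- and Lamp5-like 3319, Sst- and Vip-like 1380, Sst- and Lamp5-like 2145, and Vip- and Lamp5-like 1427. The largest was Fam19a1 (ENSMUSG00000059187, chromosome 6, 96113154 to 96657198), which fell with age in Pvalb-like nuclei (50.1 and 160 CPM at P10, 5.41 and 8.61 at P28, ALM and V1) and rose in Lamp5-like nuclei (25.0 and 26.1, then 508 and 726 CPM), a difference of 8.34 log2. The age changes of Sgpp2 (−4.11), Myo1e (−3.67) and Adamtsl5 (−3.25) were lower in Sst-like than in Pvalb-like nuclei, and those of Stk32a (3.09) and Arhgap6 (3.05) higher. For area the counts were 353, 147, 299, 273, 296 and 64 in the same order of pairs. Bmpr1b stood out, with a difference of −2.60 between Sst-like and Pvalb-like nuclei, from 30.1 and 15.9 CPM in ALM to 6.64 and 1.59 in V1 in Sst-like nuclei (P10, P28), and Angpt1 differed the other way (2.56).

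Cell classes outside the comparisons were above the limit that a count of 0 allows. Red blood cell-like barcodes made up 1.55% of the E13 library labelled positive. Excitatory-like nuclei made up 2.58% of the P2 control (0 of 4216 with doublets kept), 13.5% of the cKO, 1.63% and 2.04% of P10 ALM and V1, and 7.55% and 11.1% of P28 ALM and V1 (4.92% and 6.81% with at least 1000 genes). The P2 control held 3.98% striatal projection neuron-like and 3.73% oligodendrocyte precursor-like nuclei, and the cKO 16.8% of the subpallial projection type. P10 ALM held 1.37% striatal projection neuron-like nuclei, but 0 of 6070 with at least 1000 genes, and 1.37% oligodendrocyte-like nuclei. Oligodendrocyte-like nuclei made up 1.10% of P10 V1 and 1.77% of P28 V1 (2.90% with doublets kept).

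The E13 libraries carried the reverse of their labels. An exchange of labels fits, since the other library was out of place too: radial glia-like cells made up 0.499% of the library labelled negative, the label of progenitors, against 57.8% of the library labelled positive, although an exchange of the sorted cells before the libraries were made would look the same. Progenitors in the sort gate do not account for it, since postmitotic cells of the cortical interneuron type made up only 0.444% of the library labelled positive against 35.2% of the other. Scaling does not either, as Lhx6 stayed at −2.79 after median-of-ratios centring. The design names no biological difference that would reverse the labels, so none was tested.

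The wide differences between the P2 cKO and control libraries may come from counting. Of the 1885 genes at 100 CPM or more in the control, 22 had 5 or fewer UMIs in the cKO, and 100% of the 21 in the reference have a 3' end inside another gene of the same strand, against 1.66% of 1862 other genes, as would follow if reads over whole gene bodies were counted in the cKO library and over exons alone in the control. Loss of Mef2c as the cause is argued against by the same shift in excitatory-like nuclei (rho 0.897). For cytoplasmic RNA in the control, mitochondrially encoded UMIs per nucleus had a log2 ratio of −1.64, cKO to control. The median of 203 single-exon genes without a same-strand neighbour was −1.18, a gap of −0.46 (interval −0.69 to −0.22, bound −0.5). The gap cannot decide, because cytoplasmic RNA in the control would lower both values, so this cause stays open. Whether counting explains any of the lower Mef2c was not shown. Ratios rose with gene length, to a median of 2.53 among the longest genes (median 170 kb), and Mef2c, a long gene, went the other way. Counting does not explain all of the lower Mef2c, which stayed at −0.85 relative to excitatory-like nuclei, a class the control lacked with doublets kept. That remainder is consistent with the cKO label as a hypothesis, but other differences between 1 pair of libraries were not tested.

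For Sst, Npy and Vip RNA lower in V1 in classes that should lack it, free RNA in the ALM libraries stays open. The 3 together were lower in excitatory-like nuclei by −0.70 at P28 but by −0.34 at P10, with an interval that includes 0. Singly, Sst was lower there at P10 (−1.21, −2.21 to −0.29) and P28 (−0.88, −1.17 to −0.59), so free RNA may be part of its fall. At P10 Npy (0.87, −0.44 to 2.26) and Vip (0.01, −0.99 to 0.99) were not clearly lower. In oligodendrocyte-like nuclei the Sst intervals held 0 at P10 (−2.08 to 0.30) and P28 (−1.16 to 1.16). A UMI of these genes was found in 50% and 30.2% of excitatory-like nuclei at P10 (median 18924 and 12929 UMIs) and 76.1% and 52.3% at P28 (13947 and 10631 UMIs; ALM, V1). In oligodendrocyte-like nuclei Npy was also lower in V1 at P28 (194 and 80.8 CPM, from 31 and 138 nuclei with median depths of 2971 and 3137 UMIs), so part of its fall may be free RNA. Against excitatory-like nuclei, free RNA does not account for all of Npy in Lamp5-like nuclei (285 to 132 CPM at P28, 73.0 to 34.5 at P10). The fall in CPM was at least 5.94 times the upper bound there. In UMIs per nucleus the fall at P28 was 1.42 against 0.358 in the deeper excitatory-like nuclei (at most 0.464). Against the shallower oligodendrocyte-like nuclei it was only 1.35 times in CPM at P28 (153 and 113), but 1.42 against 0.409 UMIs per nucleus (at most 0.847). In Pvalb- and Vip-like nuclei the Npy fall at P28 (53.3 and 64.8 CPM) was below that 113, so free RNA was not excluded there. A true area difference in Npy stays open as a biological explanation, untested beyond these 4 libraries.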

How the results depend on the processing

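The alternatives that placed unnamed clusters in their closest class, subtracted excitatory-like nuclei, left out the cluster led by Adarb2 and Htr2c or the subclusters led by Nos1 and Npy, or left out genes with a 3' end in another gene were tests chosen only after the result was seen; the others were planned. No paired analysis was possible because each group had 1 library, so no replicate was shared; the age and area model already blocks each factor on the other. Of values for named genes, 333 of age kept their call and 3 lost it, and 235 of area kept it and 66 lost it; with a library left out, all 192 of age kept it, but 7 of area kept it, 152 lost it and 13 reversed. The cause was not tested except where stated. Age counts (Pvalb, Sst, Vip, Lamp5) were 6849, 4937, 1724 and 2494 by the DESeq2 Wald test, and 3583 in Vip- and 4061 in Lamp5-like nuclei after thinning. Area counts were 118, 149, 1 and 14 by the Wald test, and 0 in all classes without age in the model (30, 101, 7 and 26 at an unadjusted p under 0.05). They were 740, 922 and 41 without a filter (Pvalb, Sst, Vip), 672 and 51 at resolution 2 (Pvalb, Vip), 170, 45 and 84 after thinning (Pvalb, Vip, Lamp5), 725 and 77 with doublets kept (Sst, Vip), 42 with size factors (Vip), and 635, 71 and 86 with unnamed clusters placed (Sst, Vip, Lamp5). Left-out libraries gave 6917 to 9516, 5068 to 7272, 4334 to 4815 and 4426 to 5673 genes for age, and 0 to 0, 0 to 11, 0 to 6 and 0 to 0 for area, where dropping age from the model puts age into the fold change and the spread by construction; an arm of 1 library was assumed to vary like the other.

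With a library left out, area log2 fold changes carry age as well, so a reversal does not measure how stable area is. Those that reversed ranged from −1.66 to 3.93 (Fam19a1), −1.65 to 3.20 (Trpm3), −2.49 to 0.68 (Npy) and −2.84 to 0.29 (Prss23) in Pvalb-like nuclei, and −1.37 to 3.18 (Ppfibp1) in Sst-like nuclei. In Vip-like nuclei they ranged from −2.42 to 1.02 (Npy) and −1.74 to 3.61 (Junb). In Lamp5-like nuclei they ranged from −0.46 to 2.99 (Slc1a3), −1.72 to 3.22 (Abca8a), −0.19 to 1.80 (Nrp2), −1.50 to 2.80 (Pard3bos1), −2.19 to 0.040 (Npy) and −1.59 to 0.20 (Cck). With an estimated correlation, camera called 0 lists in every class, from 10, 7, 6 and 8 for age and 1, 3, 1 and 4 for area; fry called 0 for age in Pvalb- and Vip-like, 10 in Sst-like, 4 in Lamp5-like, and 0 for area in all classes.

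Lhx6 at E13 was at −2.79 with median-of-ratios centring and −2.58 as a mean over cells. Mef2c in the cKO was at −1.59 with median-of-ratios centring, −1.23 as a mean over nuclei, −1.45 at resolution 2, −1.18 with doublets kept, −1.72 minus nuclei that were not MGE-like, −0.85 minus excitatory-like nuclei, −1.17 without the Adarb2 cluster and −1.40 without genes with a 3' end in another gene. Minus nuclei that were not MGE-like, Tuba1a (0.13), Nme1 (0.28) and Mef2a (−0.69) reversed; minus excitatory-like nuclei, Mef2a (−0.52) and Mef2d (−0.032) reversed; without the subclusters led by Nos1 and Npy, Sst (0.23) reversed. From P2 to P10, Sst in ALM was at −4.84 with median-of-ratios centring and −5.01 at resolution 2, Sst in V1 at −5.86 at resolution 2, Sst at −2.95 (ALM) and −3.80 (V1) without the P2 subcluster led by Nos1 and Npy, and Vip at −2.22 (ALM) and −2.21 (V1) with median-of-ratios centring.

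At resolution 2 shares were 38.7% (P2 control MGE-like), 23.1% and 29.6% (P10 ALM Pvalb, Sst), 27.6% and 29.5% (P10 V1 Pvalb, Sst), 27.7% and 8.46% (P28 ALM Pvalb, Vip), and 28.4%, 13.2% and 10.2% (P28 V1 Pvalb, Sst, Vip). With doublets kept they were 49.0% (cKO MGE-like), 0% (P2 control excitatory-like), 25.6%, 7.97% and 10.9% (P10 ALM Sst, Vip, Lamp5), 25.2%, 25.1%, 6.16% and 8.52% (P10 V1 Pvalb, Sst, Vip, Lamp5), 8.76% (P28 ALM Vip), and 29.6% and 10.6% (P28 V1 Pvalb, Vip). With at least 1000 genes they were 57.2% and 0% (cKO MGE-like, CGE-like), 10.5% (P10 ALM Lamp5), 25.0%, 27.0% and 8.66% (P10 V1 Pvalb, Sst, Lamp5), 17.4% (P28 ALM Sst), 17.0% (P28 V1 Sst), 4.92% and 6.81% (P28 ALM and V1 excitatory-like) and 0% (P10 ALM striatal). Depth limits genes with few UMIs: Pvalb at P2 rested on 2.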

Other observations

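The tests of genes named here follow the fixed rules, except the lists relative to excitatory-like nuclei, whose reference was chosen only after the result was seen and was absent from the control with doublets kept. Within the E13 subpallial projection type, the library labelled positive had higher Gsx1 (7.71), a progenitor homeobox factor, Cdk6 (5.76) and Isl1 (4.77), a factor of cholinergic and striatal neurons, and lower Calb1 (−4.97), while Sst was at least 152-fold lower (0 against 990 UMIs). Nkx2-1 (0.80) was higher there too. The cells under this name may therefore differ in kind between the libraries. Microglia genes (all 5 higher, median 4.54, percentile 99.99) and astrocyte genes (4 of 5 higher, median 3.58, percentile 99.97; Gja1 5.13) were higher in the library labelled positive as a whole. Peptide and calcium-binding protein genes were lower (5 of 7, median −4.26, percentile 0; Npy −3.97).

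In the MGE-like nuclei of the P2 cKO relative to nuclei that were not MGE-like, GABA synthesis genes were higher in 7 of 8 cases (median difference 0.86, percentile 99.97), interneuron transcription factors in 16 of 25 (0.46, 100) and activity-regulated genes in all 7 (1.16, 99.9), and synaptic release genes were lower in 11 of 17 (−0.31, 1.5). Relative to excitatory-like nuclei, genes of MGE cortical interneurons were lower in all 9 (−1.45, 0.41), GABA synthesis genes in 6 of 8 (−1.01, 1.39), and axon guidance genes were higher in 16 of 27 (0.56, 100). The direction for GABA synthesis thus turned with the reference. The nuclei that were not MGE-like held 1179 CGE-like and 534 Meis2-like nuclei in the control but 3 and 2 in the cKO. Nr2f2, one of the interneuron transcription factors, was at 153 CPM in these nuclei of the control and 15.5 in the cKO. The make-up of this reference therefore sets part of the differences taken against it. At P28 Sncg-like nuclei made up 3.19% of ALM and 2.21% of V1.

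Between P2 and P10 in CGE-like nuclei of ALM, axon guidance genes were higher (median 3.4), and electron transport (−4.54), migration (−4.09) and activity-regulated genes (−3.00, percentile 0.08) lower. The random lists behind this percentile were not matched on gene length. The 22 genes nearly absent from the cKO summed to 14508 and 27562 CPM in the E13 libraries labelled positive and negative and 21013 in the P2 control, against 0.64 and 0.59 at P10, 1.32 and 1.15 at P28 and 1.67 in the cKO. In the cKO against the control, log2 ratios rose with gene length (rho 0.61 over 11326 genes), from a median of −1.51 among the shortest genes (median length 5.28 kb) to 2.53 among the longest (170 kb).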
